A study of Mus musculus with 6 samples.

How the data were processed

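Sorted c-Kit-positive bone marrow cells of 6 mouse samples were captured on a 10x Genomics Chromium instrument, which tags the transcripts of each droplet with a cell barcode. Per the labels' protocols the libraries were made with version 3 of the 3' kit. The submitters' processing notes name Cell Ranger 3.1.0 and the mouse build mm10. The files used here were the deposited list of cell barcodes and the deposited list of genes, both for the series as a whole and both without a header. Neither holds a measurement, so no unit of expression applies. By its name the barcode list is a filtered one, so barcodes that did not pass that filter are out of view. Each barcode entry is a 16-base sequence followed by a library number, and each gene entry is an Ensembl identifier, a symbol and a feature type. How cells were told from empty droplets, whether barcodes of droplets with more than one cell were removed, how the libraries were merged and which annotation release was counted is not given in the sources used here. The count matrix was not analysed here, and no doublet caller was run, since that needs counts per barcode.

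Samples were grouped by their titles into wild type, pre-leukemic and leukemic, with 2 samples each. The library numbers 1 to 6 match no sample label, and no order was assumed, so each library was treated as an unassigned sample. Libraries are reported as values with a range and a median, with no mean over a group and no test between groups. Comparisons of expression between the 3 groups were planned before the data were examined and were not made, since the matrix was not analysed here and the library numbers could not be paired with samples from the labels used here. The cell type lists, the gene lists and the rule for named genes were fixed at the same time. Without expression values the rule names Cbfb, Myh11, Kit and any list member missing from the gene list, of which there were 0. Genes named for an overlap were chosen after their values were seen.

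All computations were run in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1. The share of all barcodes in each library was given an exact Clopper-Pearson interval at 95%, and numbers of barcodes and of shared sequences an exact Poisson interval. These cover counting error only. Sequences shared by each pair of libraries were compared with numbers proportional to the product of the 2 library sizes, since random draws from one list share sequences in that proportion. The Pearson statistic was referred to 100000 multinomial draws conditional on the total, two-sided. The same total gives an estimate of the size of the list. Barcode pairs 1 or 2 bases apart were counted within and between libraries and compared with 10000 permutations of the library numbers. The sharing test was tested on simulated data with the real library sizes. In 97 of 100 simulated sets the interval held the true list size, and 2 of 100 sets had a p under 0.05. With 40 barcodes copied from library 1 to library 3, the test was past that threshold towards an excess in 100 of 100 sets. That is a large transfer within 1 pair, for which 8.26 shared sequences were expected in the real libraries. Smaller transfers, and transfers spread over the pairs in proportion to library sizes, were not simulated.

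Genes were matched by identifier, without its version, to the GENCODE M21 annotation, which is on the same build as the submitters' notes name. Coordinates are 1-based. Exons of all transcripts of a gene were merged, and the percent of its exonic bases covered by merged exons of another listed gene on the same strand was computed, over all exonic bases and over the last 500. Cell Ranger assigns a read to a gene only where one gene fits it, so such same-strand overlap can lower counts. Overlap with a listed gene on the opposite strand was counted on whole gene spans, introns included. The alternatives were leaving out shared or near-identical barcodes, leaving out each library, a looser match of sequences, distinct symbols in place of identifiers, and leaving out predicted genes. No columns were left aside as belonging to another series.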

Results

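The study profiled single bone marrow cells of the mouse that carried c-Kit, the receptor for stem cell factor that marks blood stem and progenitor cells and was used to sort them. Per the labels, 6 samples fell into 3 groups of 2: wild-type mice, pre-leukemic mice and leukemic mice with a Cbfb-MYH11 knock-in allele. Cbfb encodes the core binding factor beta subunit, the partner of the RUNX transcription factors, and MYH11 encodes a smooth muscle myosin heavy chain. The 2 genes are joined by the chromosome 16 inversion of human acute myeloid leukemia. The question the design poses is how the c-Kit-positive compartment differs between the wild-type, pre-leukemic and leukemic states. The values below come from a list of cell barcodes and a list of genes. Expression values per cell were not analysed here, so no difference between the 3 groups is reported.

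A total of 18013 cell barcodes were listed, each carrying a library number from 1 to 6. Library 4 was the largest with 4936 barcodes, 27.4% of the total (exact Clopper-Pearson 95% interval 26.8 to 28.1%). Library 6 held 4126 barcodes, or 22.9% (22.3 to 23.5%), and library 1 held 3529, or 19.6% (19.0 to 20.2%). Smaller numbers were listed for library 5 with 2267 barcodes (12.6%, 12.1 to 13.1%), library 3 with 1751 (9.72%, 9.29 to 10.2%) and library 2 with 1404 (7.79%, 7.41 to 8.20%). The median over the 6 libraries was 2898 barcodes, and the largest library held 3.52 times as many as the smallest. Doublets were not identified, so a barcode can stand for more than one cell. The intervals cover counting error only, and the depth in reads or transcripts per barcode is unknown. The labels do not pair the library numbers with the 6 samples, so these values were not averaged or compared by disease state.

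**Figure D1:**
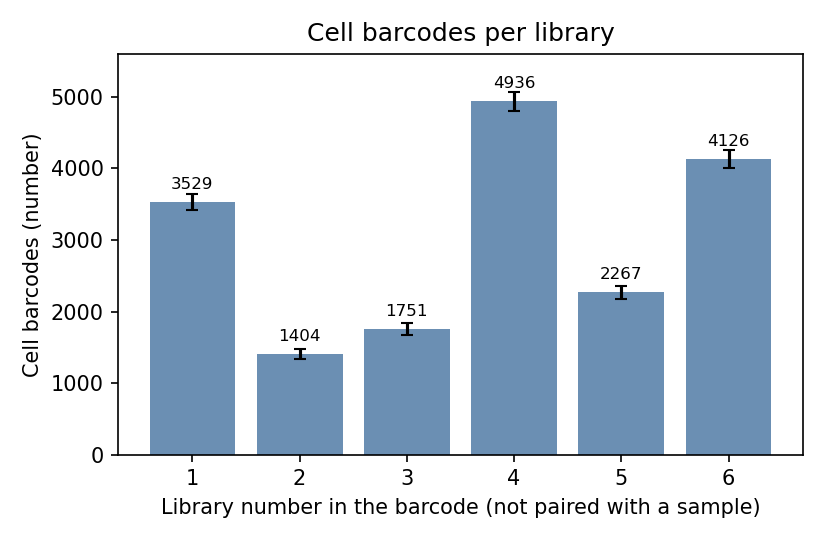
Number of cell barcodes (y axis) for each of the 6 library numbers carried in the barcodes (x axis); bars give the number listed and whiskers the exact Poisson 95% interval of that number. Library 4 with 4936 barcodes and library 6 with 4126 stand highest, and library 2 with 1404 stands lowest.

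The next comparison asked whether particular pairs of libraries shared more barcodes than their sizes predict, as barcodes passed between them would give. The 18013 barcodes comprised 17840 distinct sequences of 16 bases, of which 17668 occurred in 1 library, 171 in 2 libraries and 1 in 3 libraries. Summed over the 15 pairs of libraries, 174 sequences were shared (exact Poisson 95% interval 149 to 202). The share of a library's barcodes that also occurred in another library ranged from 1.74% in library 4 (exact 95% interval 1.40 to 2.15%) to 2.25% in library 5 (1.68 to 2.95%). Shared sequences rose with the product of the library sizes, from 4 for libraries 2 and 3 to 28 for libraries 4 and 6, against 3.28 and 27.2 expected in proportion. Over the 15 pairs, the ratio of observed to expected ran from 0.754 for libraries 3 and 5 to 1.22 for libraries 2 and 3. The conditional test of proportionality, by 100000 random draws, gave a two-sided p of 0.0024 on the side of less scatter than random draws show, with a Pearson statistic of 3.18 on 14 degrees of freedom. On the side of more scatter, the same test gave a p of 0.999. Transfer spread over all pairs in proportion to library sizes would leave this test unchanged, so it cannot address that case.

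**Figure D2:**
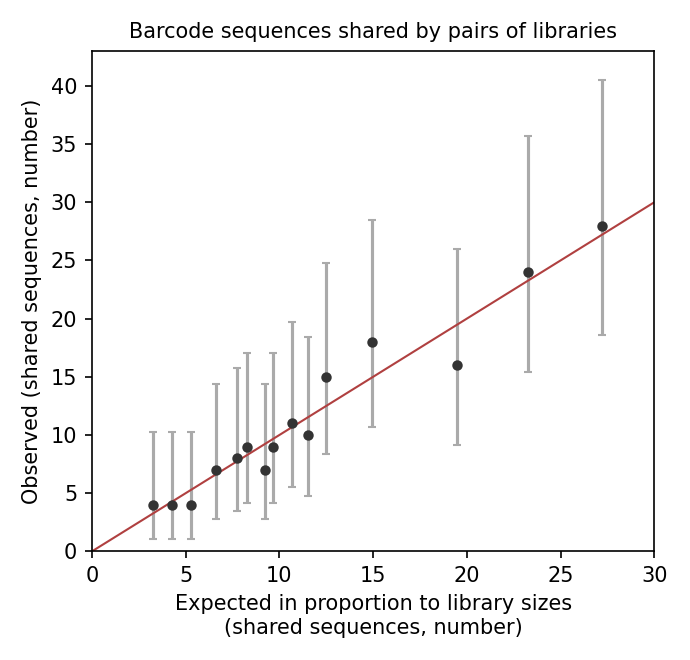
Observed number of barcode sequences shared by each of the 15 pairs of libraries (y axis) against the number expected in proportion to the product of the library sizes (x axis); points are pairs, whiskers are exact Poisson 95% intervals of the observed number, and the line marks equality. The points follow the line from 4 shared sequences against 3.28 expected to 28 against 27.2.

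Barcodes that differ by a single base within a library can arise when the transcripts of one droplet are split over 2 barcodes and counted as 2 cells. No pair of listed sequences, within or between libraries, was 1 base apart. The parts from which the sequences were built differed from each other by at least 2 bases, so this count could not have been above 0 and does not test the point. At 2 bases apart, 619 pairs lay within a library and 2498 between libraries. Permuting the library numbers over the barcodes 10000 times gave a mean of 615 pairs within a library, with 95% of permutations between 571 and 659. The two-sided permutation p was 0.862, so no excess of near-identical barcodes within libraries was detectable.

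The gene list fixed which transcripts could be counted. It held 31053 mouse genes, each with its own Ensembl identifier, and 0 identifiers of another organism. Cbfb (ENSMUSG00000031885) was listed once. In the GENCODE M21 annotation of mm10 it lies on the plus strand of chromosome 8 from 105170674 to 105217989 and is protein coding. Myh11 (ENSMUSG00000018830) was also listed once, on the minus strand of chromosome 16 from 14194535 to 14291372. Kit (ENSMUSG00000005672), which encodes the receptor used for sorting, was listed on the plus strand of chromosome 5 from 75574916 to 75656722. For Cbfb, Myh11 and Kit, 0% of the exonic bases were shared with another listed gene on the same strand. Only 1 symbol in the list contained Cbfb and 1 contained Myh11, so the fusion transcript had no entry of its own.

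All 13 gene lists chosen for this tissue were covered in full, with 10 of 10 members each and 123 distinct genes in all. This was nearly certain beforehand. All 123 are protein coding, and 21974 of the 22028 annotated protein-coding genes (99.8%) were listed. The 8 cell type lists comprised stem and multipotent progenitors, neutrophil and granulocyte progenitors, monocyte and dendritic progenitors, erythroid cells, megakaryocytes, basophils with eosinophils and mast cells, lymphoid cells, and stroma with endothelium. The remaining 5 covered the core binding factor genes, leukemia stem cell and self-renewal genes, cell cycle genes, p53 and stress genes, and the interferon response. Exons of 4 of the 123 genes overlapped exons of another listed gene on the same strand, and these 4 are named here because of that value. Gp1bb, a platelet glycoprotein gene in the megakaryocyte list, shared 92.9% of its exonic bases with Sept5 and AC133488.1, and 70.2% of the last 500 exonic bases at its 3' end. Bax, which encodes a pro-apoptotic protein, shared 12.2% of its exonic bases with Gm45808. For Ddit3, a stress-induced transcription factor gene, 6.13% was shared with AC144852.1, and for the T cell and progenitor regulator Gata3 1.94% was shared with 9230102O04Rik. None of the last 500 exonic bases of Bax, Ddit3 or Gata3 was shared. By whole gene span, introns included, a listed gene on the opposite strand overlapped 27 of the 123 genes (22.0%). The same held for 9838 of the 31011 listed genes found in the annotation (31.7%). Those 31011 include 2816 antisense RNA genes, whereas the 123 are all protein coding, so the shares are not a like comparison. The number of overlapped genes per list was lowest, at 0 of 10, in the erythroid list and the list of basophils with eosinophils and mast cells. It was highest, at 5 of 10, in the stem and multipotent progenitor, the lymphoid, and the leukemia stem cell and self-renewal lists. Mecom, Meis1, Cd34 and Flt3 were counted in both the stem and multipotent progenitor list and the leukemia stem cell list.

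Of the 31053 listed genes, 31011 (99.9%) were found by identifier in GENCODE M21, and 30541 had the same symbol there. Protein-coding genes made up 21974 of the 31011 matched genes (70.9%), long intergenic noncoding RNA genes 5459 (17.6%) and antisense RNA genes 2816 (9.08%). Immunoglobulin and T cell receptor genes and pseudogenes contributed 694 entries, including 155 immunoglobulin and 34 T cell receptor V pseudogenes. The list held 13 mitochondrial genes. MicroRNA, ribosomal RNA, small nuclear RNA and small nucleolar RNA genes had 0 entries each, and 32 of the 9941 annotated processed pseudogenes were present. Same-strand exon overlap with another listed gene affected 1224 genes (3.95%), and for 449 genes (1.45%) it covered at least 50% of the last 500 exonic bases. These shares of the 3' end bear on counts only where reads come from that end, as with the kit the labels name.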

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

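The p of the sharing test stayed under 0.05 under the alternatives that were run. The numbers of barcodes, the list size and the gene list had no threshold on p and are given as values. Leaving out sequences also found in another library removed 30 to 86 barcodes per library and moved the median from 2898 to 2839. No barcodes were 1 base apart, so removing those, or allowing 1 mismatch between libraries, changed nothing and tests nothing. Leaving out each library in turn, the two-sided p of the simulated conditional sharing test ranged from 0.0078 to 0.033, against 0.0024 with all 6, and the list size estimated from shared sequences ranged from 737320 to 774826 (an estimate chosen after seeing the data). Counting pairs 2 bases apart in place of 1 gave 619 within libraries and no excess over permutation. The gene list held 31017 distinct symbols, and 21353 genes without predicted ones. Settings intended for expression values were not run (another normalization, no filter on low counts, each replicate left out, a replicate block, and a limit on mitochondrial share). No paired analysis was possible because the barcodes carry library numbers that match no sample. The number of transcripts behind each barcode is unknown, which limits any reading of library sizes as numbers of intact cells.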

Other observations

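The conditional test of sharing between pairs of libraries was planned, while the estimate of the list size, the tests of even use of the barcode parts and the comparisons with lists of a given size were chosen after the shared barcodes and the make-up of the sequences were seen. The barcodes were built from 2 parts. The first 7 bases took 480 of 16384 possible sequences and the last 9 bases took 1536 of 262144, with bases 8 and 9 in 4 of 16 possible pairs. Each first part was seen between 14 and 54 times and each second part between 2 and 24 times, with no more scatter than even use gives (one-sided p of 0.921 and 0.807 by multinomial draws). The structure held in each library separately. In libraries 1, 2, 3, 5 and 6, 100% of barcodes had both parts present among the other libraries, and in library 4 the share was 99.9% (4933 of 4936). All combinations of the parts number 737280. The size of the list estimated from the 174 shared sequences, without use of the parts, was 748419, with a 95% interval from 645120 to 873371. The comparisons of shared numbers below rest on this same total and are not separate evidence.

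The labels name version 3 of the 3' kit, whose barcode list is several times larger than this. Drawn evenly from a list of that size, which is known from the kit and not from the files, libraries of these sizes would share 19.2 sequences, and 174 were observed, 9.08 times as many. Even draws from the combinations of the parts seen would give 176.6 shared sequences, inside the interval of 149 to 202 around the observed number. Barcodes carried over between libraries would add to the observed number. The upper end of that interval lay 25.2 sequences above the number from even draws of those combinations. This bounds carry-over only if the list is no larger than those combinations, which were taken from these same barcodes. A list smaller than those combinations, or uneven draws, would leave less room for carry-over. The total of 174 alone cannot separate a list smaller than that of version 3 from carry-over, but the parts bear on it. Each first part was seen at least 14 times and each second part at least 2 times. Under even use this argues against many unseen parts, and so against carry-over as the source of most shared sequences in the filtered list. Carried-over barcodes that did not pass the filter are out of view. A candidate explanation is that all 6 libraries were made with beads of another kit than the one named, such as the previous version of the 3' kit or the 5' kit, which share a smaller list. Which of these it was stays open, because the files used here carry no reads, and no biological explanation was tested. The kit bears on how many transcripts are recovered per cell and on which end of the gene they come from, so it is worth settling before expression of these cells is set beside that of other version 3 libraries.

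The sharing between pairs of libraries was closer to proportion than chance would usually give, with a Pearson statistic of 3.18 on 14 degrees of freedom. The planned two-sided conditional test, by 100000 random draws, gave a p of 0.0024, and the one-sided p for so even a spread was 0.0012. Leaving out library 2 raised the two-sided p of that test to 0.033. No cause for this was tested.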
